A study of Glycine max with 12 samples.

How the data were processed

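RNA-seq was done on soybean (Glycine max) roots of 2 genotypes, labelled WT and OX, grown without aluminium (CK, 0 µM AlCl3) or with 50 µM AlCl3 (Al). Each of the 4 groups held 3 libraries, 12 in all. Groups and replicate numbers were taken from the labels. The labels do not say what OX stands for, so it is called the line labelled OX throughout. They also do not say whether the 3 libraries of a group came from separate plants or cultures, so the p-values measure the spread between these libraries, which may be technical in part.

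The authors deposited 1 table of estimated counts per gene, given to 2 decimals and not scaled between libraries; the column names call them counts, per the file headers. Of all values, 13.25% were not whole numbers (tolerance 1e-06), and 43.45% of the tested genes had such a value in at least 1 library. Genes with such a value, tested or not, held 66.37% of all counts. A gene with such values is uncertain here because its reads may have been divided among near-identical copies. CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 are listed, with no role or order, per the submitters' processing notes. The genome build, the annotation, the strand setting and the step that made values with decimals are not given in the sources used here. Without a known strand setting, reads from overlapping or antisense genes could not be told apart.

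The table held 56877 rows with values, of which 56044 had Glyma identifiers and 833 had MSTRG identifiers, and 8 rows of stray text without values that were left out. No count was recorded for 9793 of the rows. The library totals ran from 15923413 to 18399566 counts, and a tested gene had a median of 194.1 counts per library. Intervals and floors cover counting error only. The file does not pair its identifiers with names. The reference table of assembly Glycine_max_v4.0 lists 59048 genes, and 0 of the identifiers matched it. The text therefore prints identifiers as the file gives them, without names, functions or coordinates, and at most 2 that rose and 2 that fell per comparison, beside a few chosen after their values were seen and the ends of a window. The chromosome and the order of genes along it were read from the Glyma identifiers.

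The main test was written for whole counts before the data were examined. Because the values were estimated counts, they were rounded to whole numbers first and the same test was kept. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 37170 genes with 99.9% of the counts. Libraries were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) fitted 1 model with a mean per group to all 12 libraries, so that the groups shared 1 estimate of the spread. The robust quasi-likelihood F-test was two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p-values are from that test unless another is named, and fold changes are given as log2 with the standard error (SE). The SE was taken as the size of the log2 fold change over the square root of the F statistic. It is thus approximate, above all for genes near 0 counts. The 5 comparisons were Al against CK in WT, Al against CK in OX, OX against WT in CK, OX against WT in Al, and the difference of the Al response between OX and WT, which is the interaction of genotype and treatment.

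The named genes were chosen by a rule fixed before the data were examined: per comparison, the called genes with the largest rise and fall in log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the groups (for the difference, without the overlap condition), and for the genotype the genes called in both treatments with the largest value of the smaller of the 2 fold changes. The rule also asked for an informative description, and its written fallback without descriptions was used. Glyma.20G176500 and the most abundant genes, among them Glyma.15G264300, were chosen after their values were seen. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. The 37 gene lists fixed beforehand were defined by words in gene descriptions, so no list could be built, and the camera tests of these lists and their alternatives were not run.

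Whether replicate numbers paired the libraries was checked by correlating the deviations of same-numbered libraries from their group means across genes. The correlations were 0.13, 0.22 and 0.36 for Al against CK in WT and 0.41, 0.12 and 0.58 for OX against WT in CK. All were over 0.1, so the numbers were taken to pair those libraries on the data alone. The pairing is uncertain, since WT_CK replicate 1 matched WT_Al replicate 2 best and WT_CK replicate 2 matched OX_CK replicate 1 best. They were 0.2, -0.004 and 0.16 for Al against CK in OX and 0.033, -0.13 and -0.0032 for OX against WT in Al. The numbers were not taken to pair those libraries. In each group, replicate 3 had the largest share of nonzero values that were not whole. That share was 19.46% in WT_CK, 20.33% in WT_Al, 19.44% in OX_CK and 19.74% in OX_Al. A number may thus mark something that libraries of all 4 groups share, which no label gives. The main model had no replicate block.

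The scripts were tested on simulated counts with means, spreads and library sizes taken from the data. In these counts, sets of 200 genes were changed by 1.5, 2 or 4 fold among 35299 genes tested. Recovery was not split by count level, so the shares below need not hold for genes with few counts in a group. The test recovered 92.4% of the 4-fold changes for Al against CK in WT, 87.9% for Al against CK in OX, 90.9% for OX against WT in CK and 89.4% for OX against WT in Al, and 69.7% for the difference. Of the 2-fold changes it recovered 40.3%, 37.3%, 31.3%, 38.8% and 5.97% in the same order. Of the 1.5-fold changes it recovered 2.99%, 8.96%, 1.49%, 5.97% and 2.99%. Most planted changes of 2 fold or less were thus missed in each of the 5 comparisons. The simulated comparison of Al against CK in WT had 93 calls, against 13908 in the real data. The adjusted p is stricter where few genes change, so these shares need not hold in the real data, least of all with Al. Between 3.2% and 7.3% of the calls fell on unchanged genes.

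The alternatives were DESeq2 size factors, no low-count filter, at least 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), a replicate block, an adjusted p under 0.01, a log2 fold change of 1 or more, a fit to only the 2 groups compared, and leaving out each library in turn. Added after the data were seen were only genes with whole values, values rounded down, and leaving out the genes of 2 windows on chromosome 16. For comparisons that share libraries, 100 sets of counts without any effect were simulated, with each gene drawn independently in each library.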

Results

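The transcriptome of soybean roots was measured in WT and in the line labelled OX, each with 0 µM AlCl3 (CK) and with 50 µM AlCl3 (Al), to look for genes tied to aluminium tolerance. Each of the 4 groups had 3 libraries. The WT_CK libraries held 16885347, 16699259 and 17862914 counts, the WT_Al libraries 17156527, 17995843 and 18048712, the OX_CK libraries 15923413, 18399566 and 17584996, and the OX_Al libraries 16373271, 16567848 and 18010354. Between 41049 and 42171 genes had a count in a library. The first principal component of log2 CPM took 64.9% of the variance and separated the Al libraries from the CK libraries. On it the OX_CK libraries, at -104.8, -64.7 and -75.0, lay between the WT_CK libraries, at -161.2, -144.9 and -115.8, and the Al libraries of both lines.

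**Figure D1:**
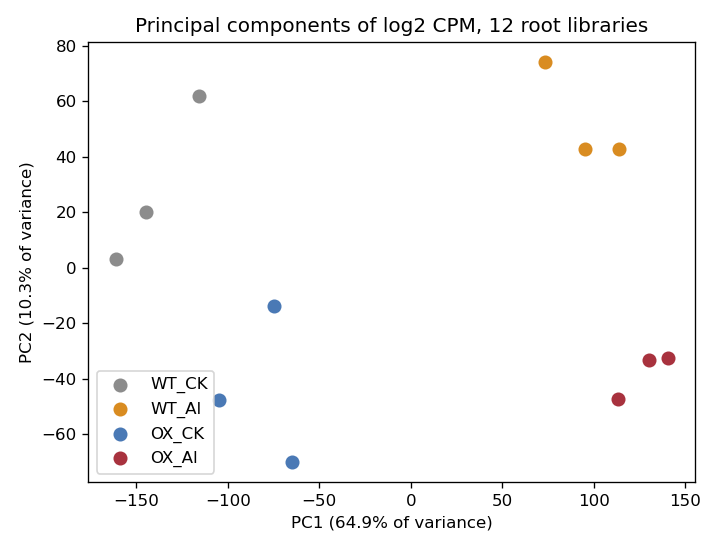
First and second principal components of log2 CPM over the 37170 tested genes; each point is 1 of the 12 libraries, coloured by group. The first component (64.9% of the variance) parts Al from CK, and along it each OX_CK library lies closer to the Al libraries than any WT_CK library does.

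The first comparison asked how WT roots respond to Al. Al raised 8007 genes and lowered 5901 of the 37170 tested, and the rises were larger, with a median log2 fold change of 1.47 against -0.92 for the genes that fell. Setting genes of a group without counts at their lower bound left these medians at 1.47 and -0.92. Glyma.08G338900 had no count in the 3 WT_CK libraries and 23.8 ± 3.6 CPM (SD, n = 3) in WT_Al, at least 439-fold higher (adjusted p = 1.06e-05). Glyma.03G098700 was likewise without counts in WT_CK and reached 10.5 ± 2.18 CPM, at least 196-fold higher (adjusted p = 4.36e-07). Among the genes that fell, Glyma.20G216800 went from 11.8 ± 4.25 to 0.111 ± 0.192 CPM, a log2 fold change of -6.57 ± 0.67 (SE, adjusted p = 1.43e-05). Glyma.17G139900 went from 122.3 ± 17.2 to 1.39 ± 0.622 CPM, a log2 fold change of -6.44 ± 0.29 (adjusted p = 3.79e-08), and is among the genes with values that are not whole. The calls were 8754 at an adjusted p under 0.01, 7847 with a log2 fold change of 1 or more and 7898 among whole-valued genes alone.

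The second comparison put the same question to the line labelled OX. There Al raised 7888 genes and lowered 5660, with median log2 fold changes of 1.35 and -0.89, and the medians with lower bounds were the same at this precision. Glyma.U032600 rose from no count in OX_CK to 16.8 ± 2.87 CPM (SD, n = 3), at least 304-fold (adjusted p = 4.65e-07). Glyma.18G095600 rose from no count to 13.5 ± 4.25 CPM, at least 246-fold (adjusted p = 9.56e-05), and had no count in any WT library, CK or Al. In WT, Glyma.U032600 had 0.0172 ± 0.0298 CPM in CK and 0.0593 ± 0.00429 in Al. Neither Glyma.U032600 nor Glyma.18G095600 was called for a difference of the Al response between the lines. All groups but OX_Al were at or near 0 counts for both genes, where that test can decide little. The missing calls therefore do not show that the lines respond alike. Glyma.11G236700 fell from 10.8 ± 5.95 to 0.348 ± 0.338 CPM (log2 fold change -4.96 ± 0.70 SE, adjusted p = 0.000225). Glyma.03G254300 fell from 29.1 ± 4.15 to 1.22 ± 0.571 CPM (log2 fold change -4.58 ± 0.45 SE, adjusted p = 1.46e-05). The calls were 8020 at an adjusted p under 0.01, 7366 with a log2 fold change of 1 or more and 7703 among whole-valued genes alone.

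Most of the Al response was common to both lines. 5959 genes rose in both and 3406 fell in both, where independent lists of these sizes would share 1699 and 899. 9 genes rose in WT and fell in OX, and 51 fell in WT and rose in OX. Across the tested genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.819 and a Spearman correlation of 0.8. Of the genes that rose in WT, 97.6% had a fold change of the same sign in OX. With a log2 fold change of 1 or more, 3843 genes rose in both and 1148 fell in both, and 1391 fell in both at an adjusted p under 0.01. Among whole-valued genes alone 3190 rose in both and 2047 fell in both.

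**Figure D2:**
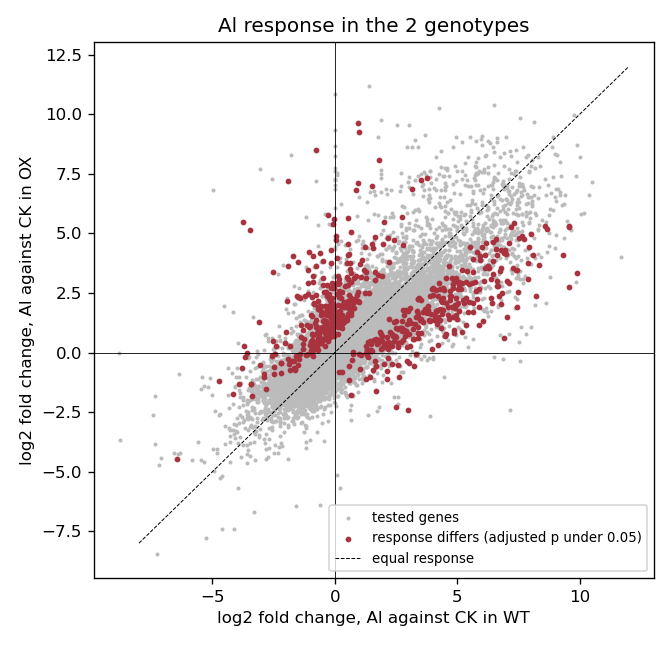
Log2 fold change of each tested gene with Al in WT (horizontal) and in OX (vertical); grey points are the 37170 tested genes, red points the 605 whose response differed between the lines, and the dashed line marks equal responses. The points follow the dashed line (Pearson 0.819 across genes), with red points on both sides of it.

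The third comparison asked how the lines differ without Al. In CK, 1090 genes were higher in OX and 556 were lower, with median log2 fold changes of 1.91 and -1.17, also with lower bounds. Glyma.16G170900 had no count in WT_CK and 7.97 ± 5.35 CPM (SD, n = 3) in OX_CK, at least 150-fold higher (adjusted p = 0.00263). Glyma.16G214500 had 0.0344 ± 0.0595 CPM in WT_CK and 15.1 ± 3.78 in OX_CK, a ratio of 422 with a counting interval of 116 to 3490 (adjusted p = 6.64e-06). Glyma.16G174900 had 12.4 ± 1.7 CPM in WT_CK and no count in OX_CK, at least 222-fold lower in OX (adjusted p = 2.25e-06). MSTRG.37489, a locus without a Glyma identifier, had 12.3 ± 1.01 CPM in WT_CK and 0.018 ± 0.0312 in OX_CK, a ratio of 663 with a counting interval of 119 to 26200 (adjusted p = 5.58e-05). The 3 chromosome 16 genes named here have values that are not whole. The total of 1646 calls fell to 723 without WT_CK replicate 2 and to 739 without OX_CK replicate 2, to 515 when only these groups were fitted and to 634 at an adjusted p under 0.01, and it was 2737 by the DESeq2 Wald test and 1029 among whole-valued genes alone. The share of calls higher in OX was 66.2%, against 56.2% with the replicate block.

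Genes that were higher in OX in CK were largely genes that Al raised in WT. Of the 1090 genes, 924 (84.8%) also rose with Al in WT and 7 fell, and of the 556 lower genes 394 (70.9%) also fell and 28 rose. Independent lists would share 235 and 88. The comparisons share the WT_CK libraries, so part of the excess may come from these. The covariance of the log2 fold changes across genes was 0.423, against 0.053 on average in 100 simulated sets without effects, and the correlation was 0.557 against 0.5. The simulated libraries were independent, without the deviations that same-numbered libraries share. The 924 genes became 535 without WT_CK replicate 1, 446 without WT_CK replicate 2 and 512 without OX_CK replicate 2, 398 at an adjusted p under 0.01, 1442 by the DESeq2 Wald test and 605 among whole-valued genes alone. The 394 became 127 without WT_CK replicate 2 and 114 without OX_CK replicate 2, 652 with the replicate block, 100 at an adjusted p under 0.01, 227 with a log2 fold change of 1 or more, 675 by the DESeq2 Wald test and 214 among whole-valued genes alone.

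The fourth comparison asked how the lines differ under Al. With Al, 1547 genes were higher in OX and 711 were lower, with median log2 fold changes of 1.45 and -1.09, also with lower bounds. Glyma.18G095600 was at least 231-fold higher in OX_Al than in WT_Al, where it had no count (adjusted p = 0.000492). Glyma.12G149800 had no count in WT_Al and 6.57 ± 2.37 CPM (SD, n = 3) in OX_Al, at least 112-fold higher (adjusted p = 0.00313). MSTRG.37489 had 11.9 ± 4.7 CPM in WT_Al and no count in OX_Al, at least 191-fold lower in OX (adjusted p = 2.21e-05). MSTRG.22386 had 16.1 ± 0.259 CPM in WT_Al and 0.23 ± 0.0876 in OX_Al, a log2 fold change of -6.07 ± 0.61 (SE, adjusted p = 9.1e-05). The total of 2258 calls fell to 1404 without WT_Al replicate 2, 1393 without OX_Al replicate 2, 1391 without OX_Al replicate 3, 1141 at an adjusted p under 0.01 and 1391 among whole-valued genes alone.

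A smaller set of genes differed between the lines in both treatments. 423 genes differed in the same direction in CK and in Al, of which 322 were higher in OX and the rest lower, where independent lists would share 45 and 11. 13 of the 322 had 3 or fewer counts over the 6 WT libraries, and 5 of the lower genes had 3 or fewer over the 6 OX libraries. Glyma.20G066400 had no count in WT and was at least 49.8-fold higher in OX in CK and at least 50.5-fold higher in Al (adjusted p = 0.000614 and 0.000243). MSTRG.32434 had no count in OX and was at least 46.9-fold lower in CK and at least 38.2-fold lower in Al (adjusted p = 0.00303 and 0.00217). Glyma.20G176500, chosen after its values were seen, ranked first by the smaller of its fold changes among the 29 genes of the 322 with a mean of at least 100 CPM in OX_CK. It had 28.6 ± 6.59 CPM in WT_CK, 103.1 ± 9.73 in WT_Al, 852.9 ± 384 in OX_CK and 1938 ± 275 in OX_Al. Its log2 fold change of OX against WT was 4.90 ± 0.34 in CK (SE, adjusted p = 2.54e-05) and 4.23 ± 0.33 in Al (adjusted p = 1.36e-05). It also rose with Al, with a log2 fold change of 1.85 ± 0.30 in WT and 1.18 ± 0.29 in OX (adjusted p = 0.000494 and 0.00802), and its values are not whole in 11 libraries. The 322 genes became 201 without WT_CK replicate 2, 145 at an adjusted p under 0.01, 539 by the DESeq2 Wald test and 199 among whole-valued genes alone. The count of lower genes became 52 without WT_CK replicate 2, 65 without WT_Al replicate 2, 51 without OX_CK replicate 2, 65, 50 and 59 without OX_Al replicate 1, 2 and 3, 156 with the replicate block, 31 at an adjusted p under 0.01, 57 with a log2 fold change of 1 or more, 186 by the DESeq2 Wald test and 56 among whole-valued genes alone.

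**Figure D3:**
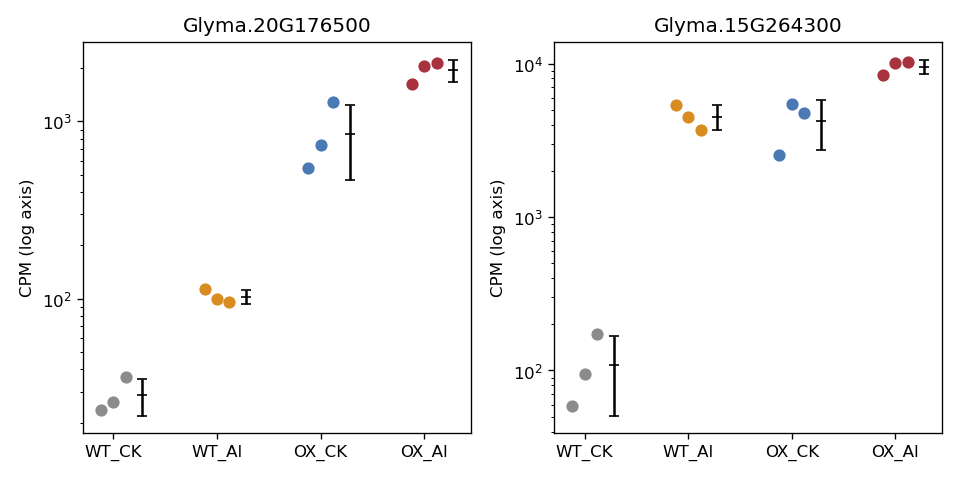
CPM on a log axis of Glyma.20G176500 (left) and Glyma.15G264300 (right) in the 12 libraries; each point is a library, and the bar beside each group is the mean ± SD of 3. Glyma.20G176500 averages 852.9 CPM in OX_CK against 28.6 in WT_CK, and Glyma.15G264300 averages 4246 against 109.1.

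Genotype differences were gathered on chromosome 16. There 42 of 1352 tested genes (3.11%) differed in both treatments (Fisher's exact test against the other chromosomes, odds ratio 3.05, adjusted p = 6.1e-08 over the 20 chromosomes). The other 19 chromosomes had adjusted p-values of 0.24 or more. In windows of 50 tested genes, the highest count was 13, from Glyma.16G170900 to Glyma.16G179500, of which 10 were higher and 3 lower in OX.

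**Figure D4:**
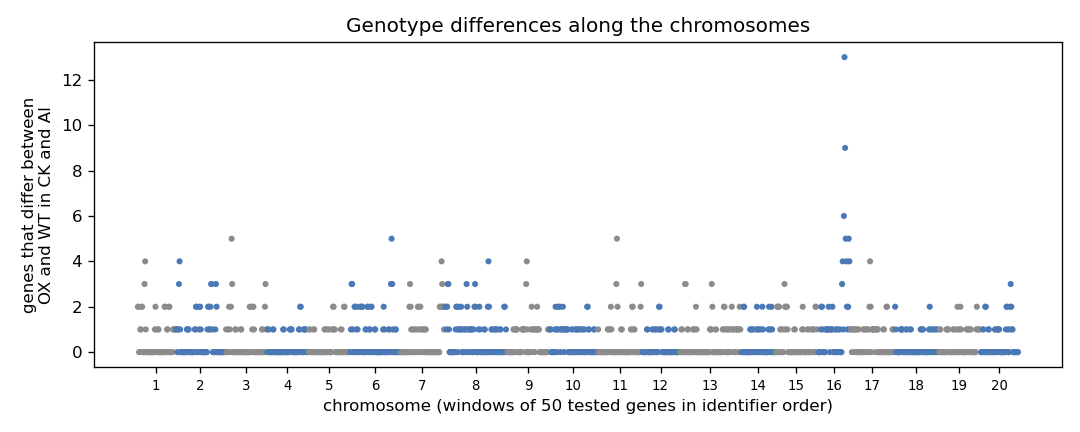
Number of genes that differ between OX and WT in both CK and Al in windows of 50 tested genes moved by 25, in identifier order; each point is 1 of 1424 windows, and colours alternate between chromosomes. The highest window, on chromosome 16, holds 13 such genes.

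The last comparison asked which genes responded to Al differently in the lines. The interaction test called 605 genes, 327 (54%) with a higher response in OX and 278 with a lower one. Over the alternatives the higher share ran up to 72.8% (adjusted p under 0.01), with 69.2% by limma-voom, and the higher genes were the fewer without WT_CK replicate 3 (47.2%), WT_Al replicate 3 (47.9%) or OX_CK replicate 1 (40.6%) and among whole-valued genes alone (45.9%). MSTRG.3391 was at 0.0701 ± 0.0784, 0.0426 ± 0.0738 and 0.0738 ± 0.0824 CPM (SD, n = 3) in WT_CK, WT_Al and OX_CK and at 29.5 ± 7.83 in OX_Al (adjusted p = 0.0303). Glyma.11G132800 was at 0.448 ± 0.729, 0.115 ± 0.0926 and 0.126 ± 0.136 CPM in these groups and at 19.8 ± 7.07 in OX_Al (adjusted p = 0.0148). Glyma.19G018500 went from no count to 5.52 ± 2.05 CPM with Al in WT and from 0.169 ± 0.0996 to 1.15 ± 0.476 in OX (adjusted p = 0.0409). Glyma.13G234400 went from 0.0357 ± 0.031 to 40.7 ± 9.14 CPM in WT and from 2.42 ± 2.88 to 25.02 ± 4.3 in OX (adjusted p = 0.0285). The call of MSTRG.3391 ended without WT_CK replicate 2 or 3, WT_Al replicate 2, or OX_Al replicate 2 or 3 (adjusted p = 0.0925, 0.307, 0.0645, 0.0632 and 0.0535), and that of Glyma.11G132800 without WT_CK replicate 3 (adjusted p = 0.506). Of the 12 fits that left out a library, the call of Glyma.19G018500 held only without WT_Al replicate 3 or OX_CK replicate 3, and that of Glyma.13G234400 only without WT_Al replicate 3 or an OX_CK library, with adjusted p-values of up to 0.121 and 0.0931 over their alternatives.

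Of the 278 genes with a lower response in OX, 196 rose with Al in both lines and 72 rose in WT and were not called in OX. 201 of the 278 were already higher in OX in CK, where their median log2 fold change of OX against WT was 2.1 (2.09 with lower bounds), and in Al the median was -0.37. Of the 327 genes with a higher response in OX, 170 rose in OX and were not called in WT, 51 rose in both, and 46 fell in WT and rose in OX. 276 of the 327 were higher in OX in Al, with a median of 1.64. The difference shares its libraries with the other comparisons, so these counts are not independent. Glyma.15G264300, chosen after its values were seen as the most abundant gene in OX_Al, had 109.1 ± 58.2 CPM in WT_CK, 4510 ± 840 in WT_Al, 4246 ± 1520 in OX_CK and 9549 ± 965 in OX_Al. Its response to Al was a log2 fold change of 5.37 ± 0.46 (SE) in WT and 1.17 ± 0.39 in OX (adjusted p = 3.79e-06 and 0.0333), and the difference was -4.20 ± 0.56 (adjusted p = 0.00352). Its call in OX ended without OX_CK replicate 1, OX_Al replicate 2 or OX_Al replicate 3 (adjusted p = 0.117, 0.085 and 0.0879) and with limma-voom (adjusted p = 0.0646), and its values are not whole in some libraries. The 605 calls became 292 without WT_CK replicate 2, 335 and 273 without WT_Al replicate 1 and 2, 389 without OX_CK replicate 2, and 323, 272 and 318 without OX_Al replicate 1, 2 and 3. They were 147 at an adjusted p under 0.01, 1440 by the DESeq2 Wald test and 392 among whole-valued genes alone.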

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

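The counts of splits and the tests of the 3 patterns below were chosen after the results were seen.

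The Al response differed between the lines for 605 genes by the interaction test. Of the genes named by rule, the adjusted p of that difference was 0.0249 for Glyma.17G139900, 0.0192 for Glyma.16G174900, 0.0303 for MSTRG.3391, 0.0148 for Glyma.11G132800, 0.0409 for Glyma.19G018500 and 0.0285 for Glyma.13G234400. The difference of Glyma.16G174900 rests on no count in OX_CK and 6 counts over the 3 OX_Al libraries, and its call ended with values rounded down (0.163), without OX_CK replicate 2 or 3 (0.068 and 0.0542) and without OX_Al replicate 1, 2 or 3 (0.0554, 0.0615 and 0.0527). That of Glyma.17G139900 ended with limma-voom (0.0546) and without WT_CK replicate 2, WT_Al replicate 1 or 2, OX_CK replicate 2, or OX_Al replicate 1 or 2 (0.0682, 0.0709, 0.0813, 0.0533, 0.0676 and 0.0973). The adjusted p was 0.00352 for Glyma.15G264300, which was picked out later.

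Of 100 splits of the libraries for the difference, drawn from 200 that deal the genotype labels within each treatment, 6 gave as many genes as the real one, itself included, a share that is not under 0.05. The highest other split gave 3325 genes against 605, but it exchanged WT and OX in Al alone, which turns the difference into the sum of the genotype effects, so the structure it shows is the genotype. The splits with 706, 1120 and 1700 genes also kept or exchanged the lines in Al and carry the genotype effect there, so they are no measure of chance for the difference. Of the 75 other splits that mixed the lines in both treatments, 1 reached the real count, with 1951 genes. In CK that split kept the replicate 1 libraries of the lines together and those of replicate 3 together, so it carries what those pairs share, although the 7 other mixed splits with its division of CK gave 0 genes. The 23 mixed splits that part all 3 CK pairs, as the real one does, gave 0 genes, and with the replicate block the real count was 728. Splits that mix the lines put the genotype difference into the spread within groups. Few calls would then follow whether or not the responses differ, so these low counts do not measure chance. For each of the other 4 comparisons the 10 splits are too few for a share under 0.05, and only 1 split, the real one, reached its count. The real counts were 13908 and 13548 for Al against CK in WT and in OX, 1646 for OX against WT in CK and 2258 in Al, and the highest other splits gave 0, 0, 94 and 0. The 94 came with WT_CK replicates 1 and 2 and OX_CK replicate 1 together. Where the numbers were taken to pair the libraries, the 3 other splits that part all pairs gave 0 genes. The other splits of these comparisons also mix the groups compared, which widens the spread, so their low counts are no measure of chance either.

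In CK, 73.3% of the genes that Al raised in WT stood higher in OX than in WT. Their median log2 fold change was 0.224. Noise drawn independently for each gene in the shared WT_CK libraries does not account for the whole pattern. The covariance of OX against WT in CK with the Al response in WT was 0.423, above the highest simulated value of 0.055. The Al response in OX shares the OX_CK libraries with OX against WT in CK, and not the WT_CK libraries. With that response the covariance was 0.188, where independent noise alone gave -0.054 on average. The simulation held no deviation that many genes of a library share. Such a deviation of the WT_CK libraries along the Al response could raise both covariances, so it stays open. A single CK library does not by itself account for the pattern, since the lowest covariance with one left out was 0.358. The count of 924 genes still fell to 446 without WT_CK replicate 2. An unrecorded growth, harvest or batch difference between the control roots of the lines may have had a part. Same-numbered WT_CK and OX_CK libraries deviated together (correlations of 0.41, 0.12 and 0.58), and 975 genes were counted with the replicate block, but a difference common to all roots of a line would be left by that block. No label gives a batch, so it cannot be told apart from genotype, which stays open.

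On chromosome 16 genotype differences lay close together. Chance position gave at most 8 calls in a window of 50 genes in 10000 shuffles against 13 observed (permutation p = 1e-04, the smallest these shuffles can give). The shuffles treated neighbouring genes as independent. Genes that rose with Al in both lines formed 1270 neighbouring pairs, against at most 993 when shuffled, so neighbours need not be independent. Neighbouring genes that change together could fill a window, and this stays open. Sharing of reads with copies stays open, as no map of the copies was used: 11 of the 15 called genes in the 2 overlapping windows with most calls have values that are not whole. In the window chosen from such genes alone, 3 of 26 genes with whole values were called (odds ratio 11.9, 95% interval 2.28 to 39.9), but windows of whole-valued genes alone held at most 4 calls, which shuffles often reached (permutation p = 0.79). Sequence differences of a line from the reference may also shift counts, and 3 lower genes beside 12 higher ones do not decide it, because either line could differ; a stretch that differs between the lines stays open as a hypothesis.

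Glyma.20G176500 is a candidate for a gene tied to what sets OX apart, a hypothesis from the same data, since the labels do not name the gene behind OX. A shift of the OX_CK roots towards the Al state leaves the Al libraries as they are, so it could not make a difference under Al. There its log2 fold change of OX against WT was 4.23 ± 0.33 (SE). That value helped to pick the gene, so it is no independent support. For its level in CK that shift stays open: its log2 ratio of OX_CK over WT_Al was 3.05, above the 95th percentile of 0.79 of the 924 genes, but it was picked for its fold changes, 1 other of the 924 lay at or above it, and another of the 29 abundant genes, not among the 924, had 3.73. Of its 10 nearest tested neighbours, 0 were higher in OX in both treatments. This argues against an effect that raised most of these neighbours by 4 fold or more, if they are not near 0 counts. In simulated data 90.9% of such changes were found in CK and 89.4% in Al. Of 2-fold changes only 31.3% and 38.8% were found, so a smaller rise of the neighbours stays open. An effect on few genes of its stretch of chromosome stays open, since only 322 of the 37170 tested genes were higher in both. Reads shared with a near-identical copy remain possible, since its values are not whole in 11 of 12 libraries.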

How the results depend on the processing

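The settings with only whole-valued genes, values rounded down and without the 2 chromosome 16 windows were chosen after the data were seen. DESeq2 size factors, no low-count filter, 5 CPM in 3 libraries, limma-voom, values rounded down and leaving out the chromosome 16 windows kept each count within 1.5 times. Of 118 alternative counts, leave-one-out apart, 82 stayed within 1.5 times and 36 moved; of 108 counts with 1 library left out, 24 moved. The counts are given in the order Al in WT, Al in OX, OX against WT in CK, OX against WT in Al, difference, rose in both lines, fell in both, higher in OX in both treatments, lower in both, higher in OX in CK and raised by Al in WT, lower and lowered. Whole-valued genes gave 7898, 7703, 1029, 1391, 392, 3190, 2047, 199, 56, 605 and 214, fewer by construction as 21073 genes were tested. An adjusted p under 0.01 gave 8754, 8020, 634, 1141, 147, then 1391 for fell in both, 145, 31, 398 and 100, fewer by construction. A log2 fold change of 1 or more gave 7847 and 7366 for Al, 3843 and 1148 for both lines, 57 for lower in both treatments and 227 for lower and lowered, fewer by construction. The DESeq2 Wald test gave 2737 for OX against WT in CK, 1440 for the difference, 539, 186, 1442 and 675 for the last 4; the cause was not tested. Fitting only the groups compared gave 515 for OX against WT in CK; the cause was not tested. With the replicate block the 5 comparisons gave 16284, 16486, 2062, 2819 and 728, and lower in both treatments moved to 156 and lower and lowered to 652; the cause was not tested. The block also ended the difference call of Glyma.19G018500 (adjusted p = 0.0701) and changed no other count by over 1.5 times and no other named call. limma-voom ended the difference calls of Glyma.11G132800, Glyma.19G018500 and Glyma.13G234400 (0.0816, 0.0653 and 0.0931) and the call of Glyma.15G264300 with Al in OX (0.0646), and put 69.2% of the differences above 0, against 54% in the main test.

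Leaving out 1 library gave ranges, in the same order, of 10303 to 15807, 9466 to 14113, 723 to 1906, 1391 to 1784, 272 to 751, 4981 to 6565, 2310 to 4610, 201 to 404, 50 to 100, 446 to 1259 and 114 to 424. Of 45 named gene results, 5 lost their call with 1 or more libraries left out (27 of 318 such fits), 4 with limma-voom, 1 without the filter and 1 with the block, and 3 calls were gained. No called value changed direction; 3 values never called took both signs (Glyma.12G217400 for OX against WT in Al, -0.772 to 0.023, and for the difference, -0.322 to 0.487, and Glyma.17G186600 for OX against WT in Al, -0.081 to 0.031). The gene list tests and their alternatives were not run, since no list could be built. Depth limits genes near 0 counts, and in simulated data few 2-fold differences between responses were found (5.97%).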

Other observations

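The tests of neighbouring genes were set before their results were seen; the tests of MSTRG loci were chosen after.

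Genes that rose with Al in both lines lay next to one another along the chromosomes more often than their number gives. There were 1270 neighbouring pairs of such genes among 36322 tested chromosome genes, 1.39 times the mean of 912 in 1000 shuffles within chromosomes, which reached at most 993. Among whole-valued genes, where sharing of reads with copies is less of a concern, there were 665 pairs against at most 598 in the shuffles. These pairs were counted after all other genes were left out, so other tested genes may lie between their members. On chromosome 3 an unbroken run of 7 genes rose in both lines, with median fitted log2 fold changes of 5.13 in WT and 4.11 in OX and whole values throughout. On chromosome 16 a run of 8 genes rose with medians of 3.47 and 2.2, and 7 of these have values that are not whole. Genes in a tandem array that respond together may give such runs, a hypothesis that needs gene descriptions.

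MSTRG loci, which carry no Glyma identifier, differed between OX and WT in both treatments in 2.65% of 641 tested loci, against 1.12% of chromosome genes (Fisher's exact test against all other tested genes, two-sided, p = 0.00184, 12 higher and 5 lower in OX). They were also called more often for Al in WT (44.1% against 37.3% of chromosome genes), with an odds ratio against all other tested genes of 1.33 (95% interval 1.13 to 1.56), beside 2.42 (1.39 to 3.96) for the genotype.

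Genes raised by Al in WT stood at medians of 0.106, 0.287 and 0.292 above the WT_CK mean (log2) in the 3 OX_CK libraries, and at -0.129, -0.002 and 0.129 in the WT_CK libraries. Within same-numbered pairs OX_CK minus WT_CK was 0.235, 0.289 and 0.163, above 0 in 3 of 3, although these genes were chosen with the same WT_CK libraries. Their median log2 fold change of OX against WT was 0.224 in CK and -0.028 in Al, and that of the genes lowered in WT -0.256 and -0.054. These values depend on the line that chose the genes: they were 0.117 and 0.164 for the genes raised by Al in OX and -0.012 and -0.218 for those lowered in OX. Among the most abundant genes, Glyma.12G217400 fell from 4995 ± 1020 to 1427 ± 719 CPM with Al in WT (SD, n = 3) and from 3619 ± 592 to 1074 ± 494 in OX (adjusted p = 0.00552 and 0.00718). Glyma.17G186600 stood at 4192 ± 770, 3695 ± 160, 4873 ± 482 and 3616 ± 332 CPM in WT_CK, WT_Al, OX_CK and OX_Al, and was not called in any of the 5 comparisons (adjusted p of 0.134 or more), although the DESeq2 Wald test called its change with Al in OX (0.0136, in a range of 0.0136 to 0.279 over the alternatives).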
